A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

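CPD-seq was used, per the labels, to map cyclobutane pyrimidine dimers (CPDs), the most frequent ultraviolet lesions of DNA, in the yeast Saccharomyces cerevisiae. Per the labels' protocols, genomic DNA was sheared, ligated to a first adaptor and blocked at its free 3' ends. T4 endonuclease V, which cuts at CPDs, and the abasic-site endonuclease APE1 then opened new 3' ends, to which a barcoded second adaptor was ligated before sequencing on an Ion Torrent machine. A read that starts at such an end places the lesion on the 2 nt directly 5' of its start, on the strand opposite the read. The labels describe 18 samples in 14 groups, of which 17 were irradiated and 1 was not. The analysis used the unirradiated library, labelled wild type (BY4741). The other 17 samples were not analysed here, so nothing was tested between genotypes, doses or repair times.

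The deposited table holds 1 line per aligned read, with the position and strand of a dinucleotide, its bases and a mapping score. The mapping score, a whole number from 0 to 42, is the deposited confidence of the placement, and the lines include scores of 0. Bowtie2 2.2.6, SAMtools and bedtools were used with the sacCer3 build, per the submitters' processing notes, which give neither their order nor their settings. The listed bases matched the reference on the listed strand for all 10581678 reads of 2 nt on the yeast chromosomes. Another 19 reads at chromosome ends covered 1 nt and were left out of counts by position. Lines of the plus strand ran in coordinate order, whereas 44.6% of the steps between lines of the minus strand went backwards, so the listed strand was taken as that of the read and the lesion was placed on the opposite strand. Reads without molecular identifiers are not independent molecules.

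Reads were counted per strand position, and densities were set over bases, over dipyrimidine sites (TT, TC, CT and CC) or over expected reads. Exact 95% intervals (Clopper-Pearson for shares and for the split of reads between strands, Poisson for densities) cover counting error only, as there was 1 library. A count of 0 was given a limit of 3 reads. No p-values were computed, and the only chance values are the percentiles of the gene lists among random lists. Genes, tRNA genes, origins of replication, centromeres and long terminal repeats were taken from the RefSeq annotation of the same genome. The annotation held no untranslated regions, so profiles were anchored at start and stop codons. The strand ratio is the density of dipyrimidine reads on the transcribed strand over that on the non-transcribed strand, summed over 5721 nuclear protein-coding genes that overlapped no other gene and lay in no transposon. Ratios of single genes on the log2 scale had 0.5 added to both read counts. Codon adaptation, used as a stand-in for expression, was computed from the reference coding sequences with ribosomal protein genes as the reference set. Repeated DNA means the rDNA, Ty elements, long terminal repeats and the 20 kb next to each chromosome end, and single-copy density is the nuclear mean outside it, 795 reads per kb over both strands.

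Before the data were examined, 9 gene lists were fixed: ribosomal proteins, glycolysis and fermentation, nucleotide excision repair, transcription elongation, RNA polymerase II subunits, histones, chaperones, meiosis and sporulation, and galactose use. Each list's median log2 strand ratio, over members with 20 or more dipyrimidine reads, was placed among 10000 random lists of the same size matched on read count. The genes named were also fixed by rule. They are the 5 highest and the 5 lowest strand ratios whose interval excluded the all-gene ratio, among genes with 500 or more dipyrimidine reads; the 5 highest and 5 lowest read densities among such genes of 500 bp or more; RAD26, SPT4, RAD16, RAD3, HIS3, LEU2, MET17 and URA3; and the highest and lowest member of each list. LYS2, FPR1, SRD1, the CUP1 genes, the mating-type genes, TRP1 and ADE2 were added after their values were seen. Alternatives fixed beforehand counted each position once, kept only mapping scores of 30 or more, left out repeated DNA, moved the dinucleotide by 1 nt, used all reads per base or TT alone, changed bins, groups, flanks and matching, and split the reads at random into 2 sets.

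After the strand ratio had been seen, a sequence model was added. It gave expected reads per strand position as a product of 3 rates: for the 7 nt at the cut (the mapped dinucleotide and the first 5 nt of the read), for the GC content and for the purine content on the read's strand of the 200 nt that the read runs into. The rates were fitted by turns in 6 rounds on nuclear positions outside genes and repeated DNA, so that no position in an annotated gene entered the fit. Untranslated regions, which the annotation lacks, were part of it, and the windows of 200 nt could reach into genes. Intervals over the model take the expected reads as fixed. The method was tested on simulated data drawn from the model for the strand ratios of 5062 genes, 200 of them with a changed transcribed strand. For simulated ratios of 0.5 and 2 the median recovered ratios were 0.505 and 2.01, and 98% and 100% of 50 genes each had intervals that excluded 1. For 0.8 and 1.25 this held for 48% and 58%, and among 4862 unchanged genes for 4.59%. The simulated reads were drawn independently, so these rates need not hold in the library, whose reads are not independent molecules. With the transcribed strand of all 5721 genes set to 0.9, the refitted model gave back 0.903, and with no change 1.002. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.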

Results

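Cells of budding yeast were studied for transcription-coupled repair, in which CPDs that stop RNA polymerase II are removed from the transcribed strand of genes, and for the part that the ATPase Rad26 plays in it. The labels describe samples of 6 genotypes taken 0, 1 or 2 hr after 125 J/m2 of UVC, or 100 J/m2 for 2 of them, beside 1 sample taken before irradiation. The irradiated samples were not analysed here. The library taken before irradiation, labelled wild type (BY4741), is the background against which lesion maps are read, and it is described with the measurements that the irradiated samples call for. It held 10586180 reads, of which 98.6% lay on the 16 nuclear chromosomes, 1.31% on the mitochondrial genome and 0.0423% on the plasmid pUC19. Reads fell on 28.2% of nuclear strand positions, with a mean of 1.53 reads per covered position. No replicate was available, and intervals are exact 95% intervals, except where named otherwise, that cover counting error only.

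The genotype was read first, from the density of reads in a gene over that in the 5 kb on either side. All 4 genes that the study mutates were present. Read density cannot tell an unchanged gene from one with a substitution, such as the labelled genotypes Rad26_K328R and rad3_K48R. RAD26 (YJR035W, chromosome X, 497355 to 500612) had 2496 reads and 0.999 times the density of its flanks (0.960 to 1.04). RAD3 (YER171W, chromosome V, 527082 to 529418), a helicase of the repair and transcription factor TFIIH, had 1773 reads and 0.968 times the density (0.923 to 1.01). SPT4 (YGR063C, chromosome VII, 617516 to 617824), a transcription elongation factor, had 287 reads and a ratio of 1.21 (1.07 to 1.35). RAD16 (YBR114W, chromosome II, 467248 to 469620), which acts in repair of untranscribed DNA, had 1988 reads and a ratio of 1.93 (1.84 to 2.01), with a flank that includes the nearly read-free LYS2.

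The 4 loci altered in BY4741 did not all follow that label. LEU2 (YCL018W, chromosome III, 91324 to 92418) and URA3 (YEL021W, chromosome V, 116167 to 116970), of leucine and uracil synthesis, had 0 reads. The limit of 3 reads corresponds to 0.00429 and 0.00481 times the density of their flanks, and the exact upper bounds are 0.00527 and 0.00591 times. HIS3 (YOR202W, chromosome XV, 721946 to 722608), of histidine synthesis, had 384 reads and a ratio of 0.796 (0.719 to 0.880), with no read over the 118 bp from 722287 to 722404. MET17 (YLR303W, chromosome XII, 732542 to 733876), of methionine synthesis and deleted in BY4741, had 1219 reads and 1.13 times the density of its flanks (1.06 to 1.19). LYS2 (YBR115C, chromosome II, 469748 to 473926), of lysine synthesis and intact in BY4741, had 6 reads over 4179 bp, 0.00174 times the density of its flanks (6.39e-04 to 0.00379). FPR1 (YNL135C, chromosome XIV, 371882 to 372226), which encodes a rapamycin-binding proline isomerase, had 30 reads, and none from 371911 to 372199. LYS2 and FPR1 were picked out after their values were seen. TRP1 and ADE2, marker genes intact in BY4741, had 1.18 and 1.13 times the density of their flanks. As the check goes against the label, the sample is called the library labelled wild type (BY4741) throughout.

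**Figure D1:**
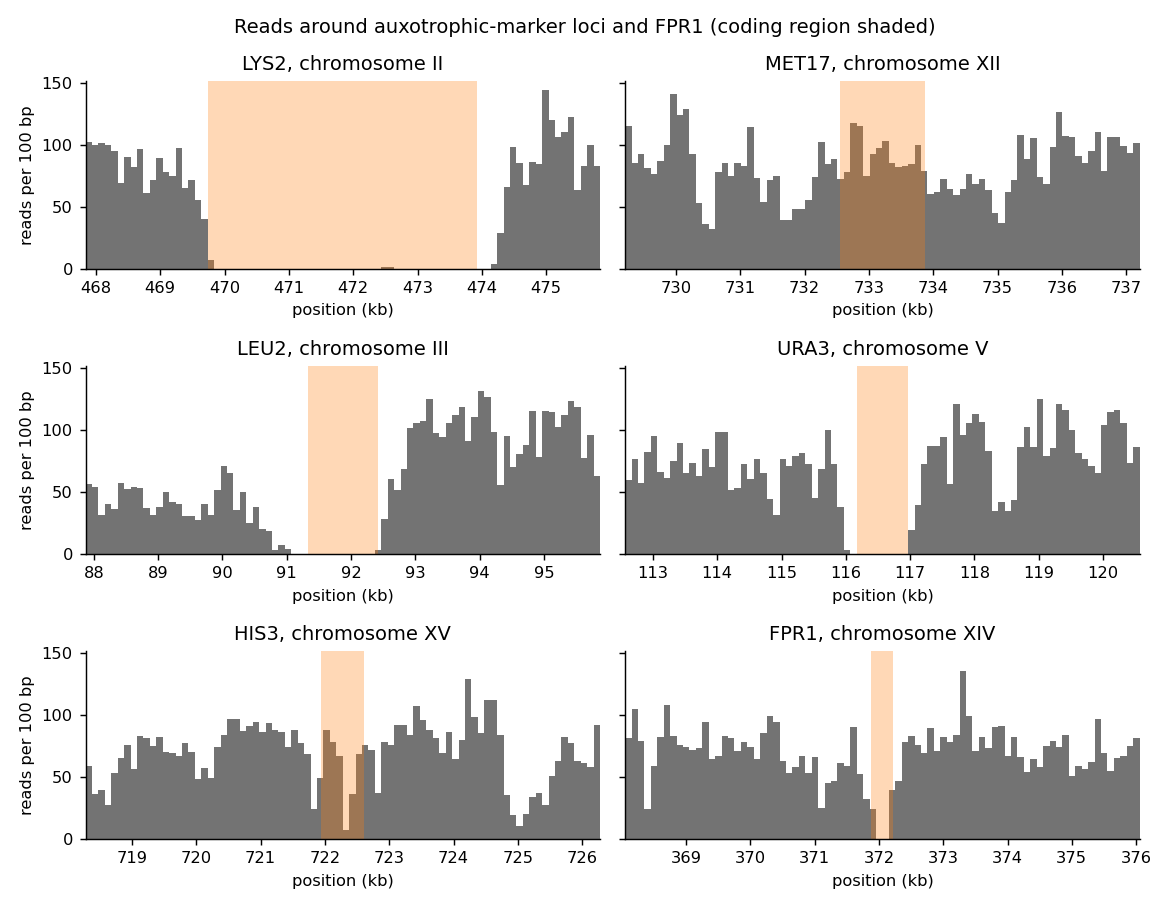
Reads per 100 bp (both strands, vertical axis) against position in kb (horizontal axis) around 6 genes, with the coding region shaded, in the library labelled wild type (BY4741). LYS2, LEU2 and URA3 are empty or nearly so, with 6, 0 and 0 reads, HIS3 and FPR1 hold a gap of 118 and 289 bp, and MET17 is covered with 1219 reads.

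The dinucleotides under the reads were close to those of the genome. Dipyrimidines, where CPDs form, made up 26.85% of nuclear reads (26.83 to 26.88%), against 26.77% of nuclear sites. At the 20 other offsets within 10 nt of the mapped position the share lay between 23.1% and 26.6%. TT was under-represented relative to its sites, at 0.957 times its share, whereas CG was the most over-represented at 1.34 times and CT followed at 1.10 times. At the first base of the dinucleotide, C was found 1.13 times as often as among sites (1.12 to 1.13), A 0.962 times, G 0.940 times and T 0.996 times. Relative to the reverse complement, TT exceeded AA by 1.05 times, TC exceeded GA by 1.07 times, CT exceeded AG by 1.14 times and CC exceeded GG by 1.16 times. On the mitochondrial genome dipyrimidines made up 29.1% of 138798 reads (28.9 to 29.4%), above the 23.4% of its sites.

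Within genes the transcribed strand carried fewer reads per site than the other strand. Over 5721 genes, 1011830 dipyrimidine reads on the transcribed strand and 880328 on the non-transcribed strand gave a ratio per site of 0.903 (0.900 to 0.905), or 1.11 with the listed strand taken as the lesion strand. The ratio was below 1 on each of the 16 chromosomes, from 0.888 on chromosome VI to 0.938 on chromosome III, and in 71.5% of the 5062 genes with 100 or more dipyrimidine reads. All reads per base gave 0.919. With expected reads from the sequence model, which was fitted outside genes, the ratio was 1.002 (0.999 to 1.0045), 49.6% of these genes lay below 1 and the median log2 ratio of these genes moved from -0.14 to 0.00. The purine content of the coding strand of these genes was 53.3%.

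By percentile among random lists, the repair and elongation genes lay lowest and the glycolytic genes highest. Of 22 measured nucleotide excision repair genes 19 had a log2 strand ratio below 0, with a median of -0.30 at percentile 0.47 of random lists, from RAD23, a damage recognition factor, at 1.17 (0.931 to 1.46) to TFB5, a TFIIH subunit, at 0.524 (0.234 to 1.16). Of 14 transcription elongation genes 12 lay below 0, with a median of -0.26 at percentile 5.44, from RPB9 at 1.24 (0.763 to 2.04) to PAF1 at 0.578 (0.456 to 0.733). Of 25 meiosis and sporulation genes 19 lay below 0, with a median of -0.22 at percentile 8.98, from the spore wall gene DIT2 at 1.29 (1.02 to 1.64), or 0.846 for all reads per base, to the recombination gene MND1 at 0.475 (0.322 to 0.703). Ribosomal protein genes had a median of -0.14 at percentile 75.2, with 90 of 134 below 0. Their highest member by log2 ratio, RPL41B, had 24 reads on the transcribed strand and 0 on the other, and their lowest, RPS28B, had a ratio of 0.469 (0.216 to 0.957), or 0.771 for all reads per base and 0.293 with a mapping score of 30 or more. Chaperone genes had a median of -0.06 (0.02 for all reads per base) at percentile 84.9, with 10 of 15 below 0, from HSP26 at 1.42 (1.00 to 2.05) to SIS1 at 0.738 (0.580 to 0.940).

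Of 18 glycolysis and fermentation genes 10 lay above 0, with a median of 0.07 at percentile 99.9 of random lists. TDH3, a glyceraldehyde-3-phosphate dehydrogenase, had the highest ratio of the list at 1.53 (1.22 to 1.93), and HXK1, a hexokinase, the lowest at 0.762 (0.622 to 0.932). RNA polymerase II subunit genes split evenly, 6 of 12 on either side of 0, with a median of 0.01 (-0.13 with each position counted once) at percentile 90.1, from RPB7 at 1.83 (1.22 to 2.77) to RPB10 at 0.543 (0.276 to 1.06), which stood at 1.11 and 0.938 for all reads per base. Histone genes had a median of -0.01 at percentile 83.6, with 5 of 10 below 0, from HHF1 at 1.17 (0.762 to 1.83) to HTA1 at 0.731 (0.492 to 1.08). Only 2 galactose genes could be measured, GAL2 at 1.22 (1.01 to 1.48) and GAL7 at 1.07 (0.822 to 1.38), with a median of 0.19 (-0.03 with each position counted once) at percentile 97.3. With the sequence model the medians of the glycolytic, repair and elongation lists were 0.02, -0.07 and 0.03, at percentiles 61.4, 6.91 and 66.3, the polymerase and histone medians were both 0.18, at percentiles 95.8 and 89.6, and the ribosomal, chaperone, meiosis and galactose medians lay at percentiles 38.8, 52.1, 42.4 and 84.0. For all reads per base the repair, elongation and meiosis medians lay at percentiles 0.08, 0.01 and 3.26, the ribosomal, chaperone and galactose medians at 97.7, 99.6 and 99.7, and the histone median at 54.4. With each position counted once the glycolytic median was -0.01.

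**Figure D2:**
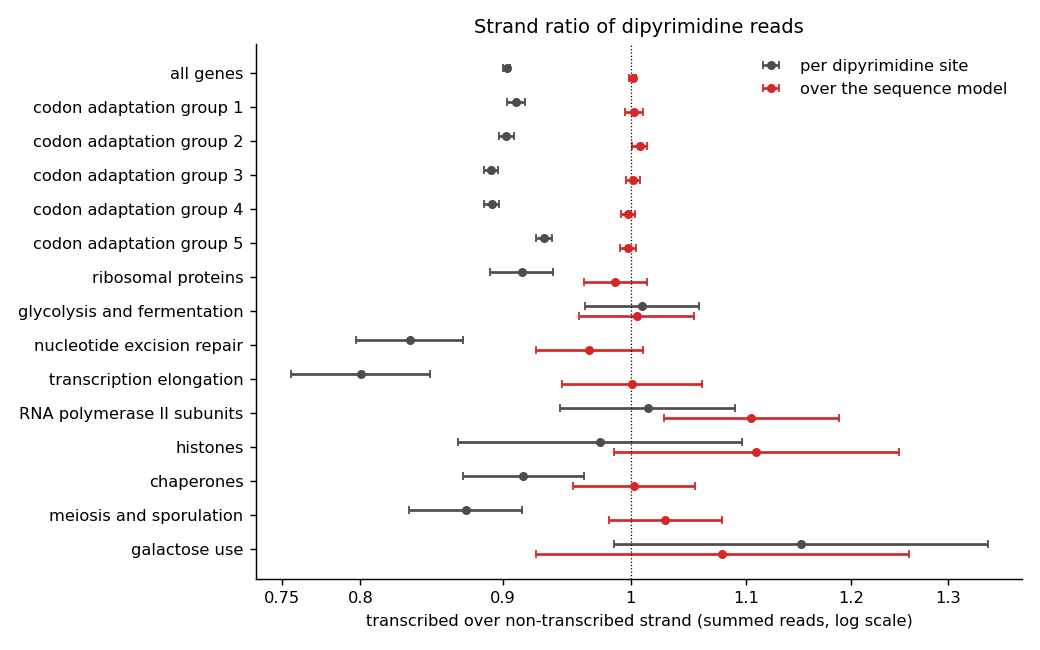
Transcribed over non-transcribed strand ratio of summed dipyrimidine reads (horizontal log axis) for all genes, 5 groups of genes by codon adaptation from lowest (1) to highest (5), and 9 gene lists, in the library labelled wild type (BY4741). Grey points are per dipyrimidine site and red points over the sequence model, bars are exact 95% intervals, and all genes lie at 0.903 per site and 1.00 over the model.

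Single genes differed in strand ratio by more than the counting error of independent reads gives. Among 1001 genes with 500 or more dipyrimidine reads, 20.9% had an interval that excluded the all-gene ratio, 120 above it and 89 below it. Independent reads would give 5% by counting error. With the sequence model 11.3% had an interval that excluded 1, 52 above it and 61 below it. The reads are not independent molecules, and how much of the excess comes from repeated copies of a molecule was not tested. The highest ratios were those of the amino acid permease gene AGP1 (YCL025C, chromosome III, 76018 to 77919) at 1.37 (1.14 to 1.63), the proton pump gene PMA1 at 1.33 (1.15 to 1.55), VBA4 at 1.30 (1.09 to 1.56), the flocculin gene FLO1 at 1.29 (1.14 to 1.47) and FLC3 at 1.25 (1.05 to 1.50). The lowest were those of UTP14 (YML093W, chromosome XIII, 83090 to 85789), a ribosome assembly gene, at 0.543 (0.463 to 0.638), the synaptonemal complex gene ZIP1 at 0.544 (0.455 to 0.651), IFH1 at 0.616 (0.520 to 0.731), the spindle pole gene SPC110 at 0.617 (0.514 to 0.742) and the nuclear pore gene MLP2 at 0.628 (0.552 to 0.715). The sequence model moved UTP14 to 0.778 and ZIP1 to 0.767, SPC110 to 0.939 and MLP2 to 0.903, and AGP1 to 1.32. For all reads per base AGP1, PMA1, VBA4, FLO1 and FLC3 stood at 1.19, 1.22, 1.07, 1.02 and 1.06. In the same setting UTP14, ZIP1, IFH1, SPC110 and MLP2 stood at 0.693, 0.600, 0.752, 0.686 and 0.702. PMA1 was at 1.12 with each position counted once. RAD26 had a ratio of 0.895 (0.766 to 1.05), RAD16 0.830 (0.694 to 0.993), RAD3 1.02 (0.848 to 1.22), SPT4 1.22 (0.695 to 2.21), MET17 0.934 (0.743 to 1.17) and HIS3 1.05 (0.710 to 1.55).

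The strand ratio did not run in 1 direction with codon adaptation, the stand-in for expression. The 1145 genes with the lowest index had a ratio of 0.910 (0.903 to 0.917), the middle group 0.891 (0.886 to 0.897) and the 1144 genes with the highest index 0.931 (0.925 to 0.937). The highest over the lowest group came to 1.02 (1.01 to 1.03, a normal approximation on the log scale). Spearman's rho across 5062 genes, which are not independent replicates, was 0.0589, or -0.0149 with the sequence model. With the sequence model the 5 groups lay between 0.998 and 1.01, and the highest over the lowest group was 0.994.

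Read density fell at both ends of genes. In 3442 genes of 1000 bp or more, dipyrimidine reads per site were lowest from 150 to 100 bp upstream of the start codon, at 0.735 times (0.726 to 0.743) the level from 200 to 500 bp inside the gene. In 3430 genes they were lowest from 50 to 100 bp downstream of the stop codon, at 0.666 times (0.657 to 0.674) the level inside. The sequence model brought these ratios to 0.914 and 0.853. Upstream of the start codon the strands ran together, at 0.319 and 0.318 reads per site in the lowest bin, and from 150 to 200 bp inside they stood at 0.425 on the transcribed and 0.470 on the non-transcribed strand. In the first 50 bp downstream of the stop codon the transcribed strand was still lower, at 0.281 against 0.343. The strands were level from 50 to 100 bp, at 0.281 and 0.282. Farther downstream the order turned, with 0.329 on the transcribed and 0.285 on the non-transcribed strand from 150 to 200 bp. Flanks were not cleared of neighbouring genes, so bins outside a gene can hold coding DNA of another. A position can also count for more than 1 gene, which the intervals do not allow for. Over the sequence model the values from 150 to 200 bp were 1.06 and 1.07 inside the gene and 0.982 and 1.03 downstream. In the first 50 bp of the gene the strands stood at 1.02 and 1.14 and from 100 to 150 bp at 1.04 and 1.11. Downstream of the stop codon they stood at 0.952 and 0.860 from 50 to 100 bp and at 0.990 and 1.14 from 200 to 250 bp.

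**Figure D3:**
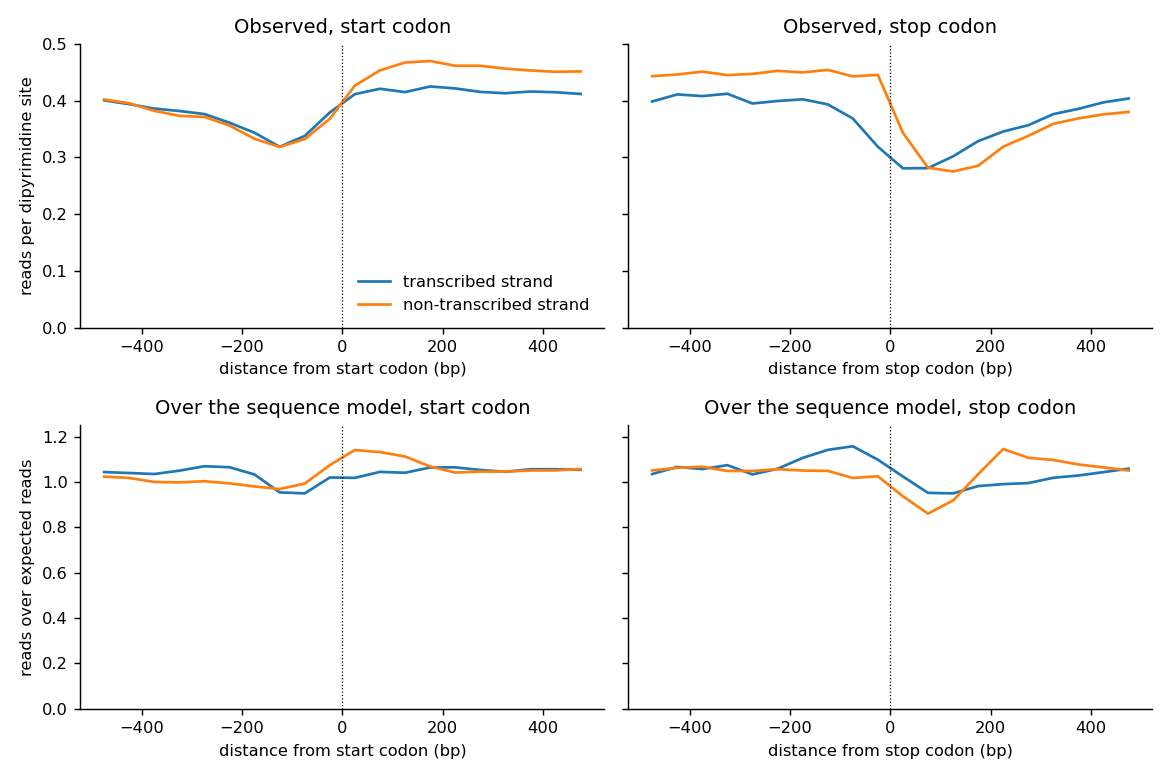
Dipyrimidine reads per site (top) and over expected reads of the sequence model (bottom) by strand, in 50 bp bins, against the distance in bp from the start codon (left, 3442 genes) and the stop codon (right, 3430 genes), in the library labelled wild type (BY4741). The lowest bins lie 150 to 100 bp upstream of start codons and 50 to 100 bp downstream of stop codons, at 0.735 and 0.666 times the level inside the genes.

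Among nuclear regions, the rDNA and the centromeres lay furthest from the nuclear mean in read density. The rDNA, the array of ribosomal RNA genes on chromosome XII, held 811601 reads on the 17357 bp of its reference copies, 54.1 times the nuclear mean (53.9 to 54.2). Divided by the single-copy density and the unit length of 9137 bp, this corresponds to 112 units (111.5 to 112.0), or 94.8 with the sequence model. Centromeres, which are 25.2% GC, had 338 reads and 0.207 times the nuclear mean (0.186 to 0.231). Replication origins had 0.817 times (0.811 to 0.823), tRNA genes 1.05 times (1.03 to 1.06), long terminal repeats and Ty elements 0.930 times (0.927 to 0.934), chromosome ends 1.008 times (1.006 to 1.011), coding regions 0.973 times (0.973 to 0.974) and DNA outside genes 0.850 times (0.849 to 0.851). The mitochondrial genome lay at 1.87 times (1.86 to 1.88). With a mapping score of 30 or more the rDNA fell to 4.61 times, long terminal repeats and Ty elements to 0.147 times, chromosome ends to 0.509 times and tRNA genes to 0.970 times. With each position counted once the rDNA stood at 3.51 times. That count allows at most 1 read per strand position, which caps a class this dense, so the value cannot measure its excess. Coding regions stood at 1.06 and long terminal repeats and Ty elements at 1.01 times the single-copy mean, which leaves out the rDNA. Against the single-copy density with the sequence model, centromeres stood at 0.556, replication origins at 1.10 and DNA outside genes at 1.03. Origins and DNA outside genes kept their repeated DNA, rDNA included, so these values do not describe single-copy DNA alone. With a mapping score of 30 or more they stood at 0.606 and 0.790 times the nuclear mean.

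Among genes of 500 bp or more with 500 or more dipyrimidine reads, those with the highest read density lie in or beside repeated families, and those with the lowest are AT-rich. YHR054C (chromosome VIII, 213185 to 214249) and RSC30, in and beside the CUP1 repeat, had 3745 and 1816 reads per kb. The subtelomeric helicase genes YRF1-1, YRF1-5 and YRF1-8 had 1628, 1627 and 1624 reads per kb. The lowest of these genes were SCC2 at 609, ZIP1 at 616, RPM2 at 622, SPC110 at 624 and APL5 at 631 reads per kb, with a GC content between 33.8% for RPM2 and 35.1% for APL5, against 39.1% around coding positions. The model took these 5 genes to between 0.916 for SCC2 and 1.08 for SPC110 times the expected reads.

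Reads within 2 kb of the 352 annotated replication origins were 1.31 times as dense as those over 10 kb away (1.31 to 1.32). Without repeated DNA, which holds the origins of the rDNA, the ratio was 1.009 (1.006 to 1.011), and with the sequence model as well 1.04 (1.03 to 1.04). With repeated DNA kept and a mapping score of 30 or more it was 0.981. On the left of origins the plus strand carried 50.4% of reads (50.2 to 50.5%) and on the right 49.5% (49.3 to 49.6%), against 50.8% and 49.1% in the model. The 1000 most covered strand positions held 0.577% of nuclear reads (0.573 to 0.582%), and all 1000 lay in the rDNA. Without repeated DNA the 1000 most covered held 0.187%. Of the 24512 positions with 10 or more times the mean of covered positions, 98.2% lay in the rDNA.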

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

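All tests in this part were chosen after the result was seen. Reads that align to pUC19, a bacterial cloning plasmid outside the yeast genome, enter no comparison of the report and exceed the limit of a count of 0. The library labelled wild type (BY4741) held 4483 of them, 0.0423% of all reads, and 55.5% (54.0 to 56.9%) lay at dipyrimidines, where nuclear reads had 26.9%; the share of dipyrimidines among the sites of the plasmid is not known here. TT was read 9.56 times as often as AA (7.93 to 11.6), TC 4.85 times as often as GA, CT 2.36 times as often as AG and CC 2.08 times as often as GG.

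A sequence preference shared by all reads would give the nuclear reads the same excess, but there TT over AA was 1.05. Mitochondrial reads showed an excess as well, smaller than that of the plasmid. Among them TT over AA was 1.72 and dipyrimidines over dipurines came to 1.54 (1.51 to 1.56). Yeast and plasmid reads carried over together from irradiated libraries cannot be excluded: dipyrimidines over dipurines came to 1.09 in the nuclear genome, against at most 1.04 at other offsets, and a small carried share would be hidden in that baseline. Lesions on the plasmid itself are a candidate explanation: on pUC19 dipyrimidines exceeded dipurines by 4.49 times (4.09 to 4.93) at the mapped position and by at most 1.89 times 2 to 6 nt away. When moved by 1 nt away from and towards the read, the excess was 3.03 and 2.57 times. Plasmid reads carried over from irradiated libraries would show such an excess too, so these values cannot tell them apart. How the plasmid came into the library is not given in the sources used here, and carry-over of plasmid reads, alone or with yeast reads, stays open. No biological explanation was tested.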

How the results depend on the processing

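The sequence model, the density over single-copy DNA and the listed strand taken as the lesion strand were chosen after seeing the data; the other settings were fixed before. Against the counting intervals of the main values, 109 values for the design's comparisons stayed inside, 84 moved and 17 crossed 1 (or 0 on the log2 scale) from an interval that excluded it; for single genes and list percentiles 120 stayed, 38 moved and 1 crossed the all-gene ratio from an interval that excluded it. Crossings from an interval that held the limit are counted as stayed or moved. The intervals are narrow at this depth, so small moves count, and where no value below shows a cause, the cause was not tested. Depth limits single genes, for which a simulated ratio of 0.8 was seen in 48% of 50 genes when reads were drawn independently. No paired analysis was possible because the values come from 1 library and no test.

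The strand ratio of 0.903 was 0.869 with a mapping score of 30 or more, 0.921 with each position counted once, 0.919 for all reads per base, 0.907 for TT, 0.907 as the median of genes, 0.915 without gene ends, 1.002 over the sequence model (interval 0.999 to 1.0045) and 1.11 with the listed strand as the lesion strand. Highest over lowest codon adaptation was 1.04 with the score minimum, 1.05 for all reads and 0.994 over the model. The dipyrimidine share of 26.9% was 26.8% counted once, 26.9% without repeated DNA, 24.4% and 25.9% when moved by 1 nt towards and away from the read, 29.1% in mitochondrial reads and 24.6% on the listed strand; the value of 1.13 for C was 1.09, 1.12 with the score minimum, 1.11 without repeats and 1.04 on the listed strand. List medians moved with the score minimum to -0.38 (repair), -0.41 (elongation), -0.14 (chaperones) and -0.38 (meiosis); counted once to -0.014 (glycolysis, across 0), -0.16 (elongation) and -0.13 (polymerase, across 0); for all reads to -0.10 (ribosomal) and 0.016 (chaperones, across 0); over the model to -0.0068 (ribosomal), -0.074 (repair), 0.032 (elongation, across 0), 0.18 (polymerase), 0.18 (histones, across 0) and -0.010 (meiosis); and in random sets of reads to -0.35 (elongation), -0.29 (histones), -0.15 and -0.16 (chaperones), and 0.46 and -0.10 (galactose, the latter across 0). DIT2 fell to 0.846 for all reads per base, below the all-gene ratio.

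With the score minimum, which kept 67.5% of reads, mitochondrial reads made up 1.15% and rDNA reads 0.656%, the lowest bins were 0.636 upstream and 0.579 downstream, tRNA genes stood at 0.970, LTRs and Ty elements at 0.147, centromeres at 0.163, origins at 0.606, chromosome ends at 0.509, rDNA at 4.61, coding regions at 1.08, DNA outside genes at 0.790, density near origins at 0.981 and the 1000 most covered positions at 0.550%. Counted once, the bins were 0.767 and 0.708, tRNA genes 1.11, LTRs and Ty elements 1.04, centromeres 0.266, ends 1.08, rDNA 3.51, coding 1.04, outside genes 0.877 and near origins 1.01. The rDNA value is capped in this setting, as a strand position counts at most 1 read. Over the single-copy mean, tRNA genes were 1.14, LTRs and Ty elements 1.01, origins 0.890, ends 1.10, rDNA 58.8, coding 1.06 and outside genes 0.926, since that mean leaves out the rDNA. Over the model, the bins were 0.914 and 0.853, LTRs and Ty elements 1.09, centromeres 0.556, origins 1.10, ends 1.06, rDNA 49.9, coding 1.02, outside genes 1.03, near origins without repeats 1.04, HIS3 0.640 and MET17 1.03. The classes of origins and of DNA outside genes keep their repeated DNA, rDNA included, in these values. For dipyrimidine sites, LTRs and Ty elements were 0.969, centromeres 0.176, ends 1.02, rDNA 52.8, outside genes 0.848 and near origins 1.30. All reads put the upstream bin at 0.745. Density near origins was 1.01 without repeated DNA and 1.34 within 5 kb, MET17 was 1.21 against 20 kb flanks, and the most covered positions held 0.187% without repeats, 0.0819% for the top 100, and 0.600% and 0.608% in random sets. DNA outside genes was 0.851 and 0.849 in those sets.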

Other observations

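The tests on the genotype and on the strand ratio in this part, and the regions named first, were chosen after the results were seen. The mating-type genes alpha1 at HML and MAT (HMLALPHA1, chromosome III, 13282 to 13809, and MATALPHA1, 200442 to 200969) had 456 and 441 reads, 1.09 and 1.05 times the single-copy density, and HMRA1 (293835 to 294321) had 225 reads, 0.583 times. With the sequence model these genes stood at 1.11, 1.07 and 0.857. The alpha2 genes at HML and MAT stood at 0.735 and 0.864, or 0.881 and 1.03 with the model. The read density of the CUP1 genes, of copper resistance and annotated in 2 copies, corresponds to 14.8 copies, or 16.6 with the sequence model. Besides LYS2, LEU2, URA3, HIS3 and FPR1, runs of at least 100 bp without reads lay only between 148648 and 151521 on chromosome III, over the end of SRD1 and beside it. Single-copy density ran from 0.969 times the mean on chromosome IV, the longest, to 1.06 times on chromosome I, the shortest. Mitochondrial reads had CG at 2.47 times and CC at 1.62 times the share of sites, and TT 1.72 times as often as AA (1.69 to 1.76).

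The present and absent loci go against the labelled strain. A mixture with BY4741, which carries LYS2, would leave LYS2 partly covered, but it had 0.00174 times the density of its flanks, with an upper bound of 0.00379. A mixture of strains that all lack LYS2 would leave it empty too, so this value cannot exclude one. Reads of LYS2 placed elsewhere because its sequence is repeated would need copies, but 0% of its 4130 stretches of 50 nt occur elsewhere in the nuclear genome. A strain other than the labelled one, or a mixture of such strains, remains a candidate explanation. BY4741 is MATa, for which alpha1 at HML and MAT over a1 at HMR, per locus and over the sequence model, would be 0.25. The value was 1.27 (1.10 to 1.48), nearer the 1 of a MAT alpha strain, although its interval excludes 1 as well. Whether the irradiated wild-type samples share this genotype was not analysed here.

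The lower density on the transcribed strand, with a ratio of 0.903, lies in an unirradiated library. Transcription, with codon adaptation as its stand-in, would leave a low ratio in the genes with the highest index. Over the model these had 0.998 (0.991 to 1.00), while a simulated ratio of 0.9 was returned as 0.899 in that group. The simulation changed reads only within annotated genes, whereas the fit also used untranslated regions, which the annotation lacks. An effect of transcription there could enter the fitted rates, so these values do not exclude transcription. Cut-site sequence and GC content alone left the ratio at 0.948 (0.945 to 0.951), and purine content alone left it at 0.963 (0.960 to 0.966). With the purine content of the read added it was 1.002 (0.999 to 1.0045), so base composition is a candidate explanation for the mean ratio. Outside genes the fitted rate was 0.828 for reads with 25 to 27.5% purine, 1.07 for 42.5 to 45% and 0.720 for 65 to 67.5%. However, the mean ratio averages differences in both directions near gene ends. The transcribed strand stood at 1.02 and the other strand at 1.14 in the first 50 bp. From 100 to 50 bp before stop codons they stood at 1.16 and 1.02. No cause was tested for these differences.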
